A study of Caenorhabditis elegans with 33 samples.

How the data were processed

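Transcripts of whole animals were measured by RNA-seq. Per the labels' protocols, total RNA was extracted with spin column kits from whole young adult or L4 N2 animals, and strand-specific paired-end libraries with fragments near 350 bp were sequenced on an Illumina HiSeq instrument with 150-base reads. Per the submitters' processing notes, STAR and DESeq2 1.22.2 were used, with no role given for either. The settings and version of STAR, the selection of RNA before library making, the genome build, the counting program and its strand setting are not given in the sources used here. The deposited values are gene counts, which the authors made from the reads: they were whole numbers for 46778 identifiers in each of the 33 libraries, with no normalisation. Of these identifiers 46603 were found in the WBcel235 annotation, from which gene positions were taken, and 43818 had a gene symbol there.

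Samples were grouped by generation and treatment from their labels, in 11 groups of 3 libraries. The labels call these biological replicates and do not say whether they came from separate irradiations, so the p-values measure only the spread between libraries. The fit pools this spread over the 11 groups, so it is not that of the libraries compared alone. Within groups no library appeared to be a copy of another: the chi-square per degree of freedom over genes was at least 8.5 in each of the 33 pairs of replicates. It ran from 14.7 to 20 in F1 exposed and from 10.1 to 176.2 in F3 exposed animals, so the spread was unequal between groups. Pairs from different groups were not compared in this way. Total counts of 27.7 to 60.8 M per library limit the precision, and genes near 1 CPM rest on few counts. The totals may overstate the precision of F3 recovery replicate 3 and F3 control replicate 3. Their numbers of genes without a count matched 6.18 M and 13 M reads. Up to 0.0267% of the counts of a library lay in genes that were not tested.

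Counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 (robust dispersion and robust quasi-likelihood fit) in R 4.3.3, with TMM scaling. All 33 libraries entered 1 fit with 1 coefficient per group, which left 22 residual degrees of freedom. The filter was filterByExpr on the 11 groups and kept 17627 genes, 16800 of them with a symbol. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes kept were called, with no threshold on the fold. The common biological coefficient of variation was 0.119. Levels are given as CPM, counts scaled to the library size with the TMM factors, and fold changes came from the fitted model. The standard error of a log2 fold change was calculated back from its size and the F statistic, and is approximate. Folds of genes near 0 counts depend on edgeR's prior count. A principal component analysis of log2 CPM (prior count 2) put 27% and 18.1% of the variance on the first 2 components.

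The 13 planned comparisons were exposed against control in F0 to F3, recovery against control and exposed against recovery in F1 to F3, and the change in the exposed against control difference from F0 to F1, F2 and F3. These comparisons, the test, the filter, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where stated. The averages over 4 and 3 generations were chosen after the data were seen.

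Lists of genes by family, pathway, tissue or sex, 36 in all, were tested with camera (limma 3.58.1) with a preset correlation between genes of 0.01 and again with an estimated one, and p was adjusted over the 36 lists of a comparison. Over the 13 planned comparisons the preset correlation gave 204 list calls and the estimated one 3: heat shock proteins in F1 exposed against control, and glutathione S-transferases with antioxidant genes and F-box with MATH genes in F1 exposed against recovery. The list of mitochondrially encoded genes was rebuilt from the annotation after the data were seen, because its symbols did not match. Its median entered the heat map, and 2 of its 12 genes were called in F3 exposed against recovery, both higher. Members of families with near-identical sequences (small heat shock, major sperm protein, F-box, MATH and collagen genes) may share reads, and their separate levels are uncertain, as are those of overlapping genes.

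By the fixed rule, genes were named in each comparison within a generation if they were called, their 3 libraries in 1 group all lay above the 3 of the other, the mean was at least 1 CPM in the higher group and they had a symbol of letters and a number. Of these the 10 largest changes each way were taken, with up to 4 members of the smallest p from each list, *egl-1*, *ced-13* and *cep-1*. For the differences between generations the 5 largest changes each way were taken, without the condition on overlap. The text names fewer than the rule gives, and among these it prefers genes whose calls held in other settings, a choice made after the data were seen. The rule named 151, 155, 156 and 154 genes for exposed against control in F0 to F3. Of these 36, 45, 106 and 69 were called and 35, 28, 100 and 61 lost the call in at least 1 setting. The corresponding numbers were 156, 157 and 155 named, 52, 50 and 43 called and 40, 50 and 42 lost for recovery against control, and 155, 142 and 155 named, 51, 0 and 55 called and 47, 0 and 55 lost for exposed against recovery. For the differences between generations 144, 151 and 146 were named, and all of the 6, 46 and 8 called ones lost the call in some setting. *R09E10.2*, *aip-1*, *pmp-1*, *dhs-28* and *hrg-4* as genes of the average over 4 generations were chosen after their values were seen.

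Overlaps were counted as genes called in the same direction in both comparisons and set beside the overlap of independent lists. For exposed and recovery animals, which share 3 controls, unchanged groups were simulated 20 times against shared controls. The alternatives fixed at the start were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, a filter of 5 CPM in 3 libraries, only the libraries of the generations compared, the replicate number as a block, and each library left out in turn. Added after the data were seen were a cuticle score per library (mean log2 CPM of cuticle collagen and moulting genes) as a covariate, the log2 share of ribosomal RNA counts as a covariate, and a fit without F3 recovery replicate 3 and F3 control replicate 3. The block, covariate and left-out fits kept the 17627 genes, and the covariate fits also kept the TMM factors, which the left-out fits computed anew. Size factors in place of TMM shifted the median of all genes by at most 0.044 on the log2 scale in any comparison.

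The test was tried on simulated counts for the F0 exposed against control comparison, with 200 of 17472 genes changed. It recovered 61.2%, 80.6% and 100% of genes changed 1.5-fold, 2-fold and 4-fold, with 6 false calls among 167. DESeq2 recovered 62.7%, 88.1% and 100%, with 21 false calls among 188. For the difference between F1 and F0 responses edgeR recovered 35.8%, 68.7% and 100%, with 5 false calls among 141. The changed genes were drawn from those with a mean of at least 1 CPM. Each gene was simulated independently with the dispersions of the fit. Shifts that many genes of a library share were absent, so false calls from such shifts were not measured.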

Results

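RNA-seq counts of whole *Caenorhabditis elegans* of the wild-type N2 strain were compared between animals grown under chronic gamma radiation and unirradiated animals over 4 generations. Radiation was given at 50 mGy per h for 65 h, from the synchronised embryo to the L4 larva or young adult, in cultures kept at 19 °C. Exposed animals were irradiated in each generation from F0 to F3. Recovery animals descended from a generation irradiated in F0 and were sampled unirradiated in F1, F2 and F3. Controls were never irradiated. The 11 groups held 3 libraries each, 33 in all. Total counts per library ran from 27.7 to 60.8 M (median 37.3 M). Ribosomal RNA genes took 3.19% to 24.3% of the counts of a library. F3 recovery replicate 3 had 18240 genes with a count and F3 control replicate 3 had 19610, against at least 20503 in the other 31 libraries.

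The first question was which transcripts differed between irradiated and control animals within a generation. In F0 the calls were nearly all rises, and they included glutathione S-transferase, antimicrobial peptide and lipid metabolism genes and 2 small heat shock genes. The small heat shock genes *hsp-16.48* (WBGene00002020) and *hsp-16.1* (WBGene00002015), the genes meant by these symbols throughout, rose 5.26-fold and 5.19-fold, from 0.613 ± 0.0658 to 3.24 ± 1.84 CPM and from 0.775 ± 0.196 to 4.06 ± 2.14 CPM (mean ± SD, n = 3; edgeR adjusted p = 0.015 and 0.017). Each symbol has a second gene of near-identical sequence, so how the reads were divided is uncertain. The second gene of *hsp-16.48* (WBGene00002019) was at 1.91 ± 1.21 CPM in exposed and 1.02 ± 0.53 CPM in control animals, and that of *hsp-16.1* (WBGene00002017) at 1.33 ± 0.172 and 0.879 ± 0.173 CPM (edgeR adjusted p = 0.46 and 0.54). Neither second gene was called in any of the 13 planned comparisons. Of 28 heat shock genes 2 were called in F0, both higher (6, all higher, adjusted over the list alone; list adjusted p = 0.58 with an estimated correlation). The acyl-CoA oxidase gene *acox-1.5*, of peroxisomal beta-oxidation, rose 1.74-fold from 17.1 ± 1.18 to 29.8 ± 0.836 CPM (log2 fold change 0.8, SE 0.11, edgeR adjusted p = 0.00022). The protein-coding gene *R09E10.2*, chosen after its values were seen, rose 4.57-fold from 5.87 ± 1.03 to 26.9 ± 2.82 CPM (log2 fold change 2.19, SE 0.18, edgeR adjusted p = 1.1e-08). The long non-coding RNA *linc-142* rose 3.23-fold (log2 fold change 1.69, SE 0.33, edgeR adjusted p = 0.014).

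Of 109 tested lysozyme and antimicrobial peptide genes, 15 were called in F0, all higher (32 higher and 1 lower adjusted over the list alone). They included *fipr-10* at 1.72-fold, *fipr-8* at 2.06-fold and the saposin-like gene *spp-25* at 1.49-fold. The list stood above other genes by camera (adjusted p = 9.8e-10), with an adjusted p = 0.16 with an estimated correlation. Of 66 glutathione S-transferase and antioxidant genes 5 rose (7 adjusted over the list alone), among them *gst-36* at 1.56-fold and *gst-13* at 1.44-fold (list adjusted p = 0.24 with an estimated correlation). Lipid metabolism gave 6 rises among 95 genes (12 rises and 1 fall adjusted over the list alone), with *lbp-2*, a fatty acid binding protein gene, at 1.34-fold (list adjusted p = 0.16 with an estimated correlation). The haem transporter gene *hrg-4* rose 1.76-fold, *ugt-30* 1.74-fold and the C-type lectin gene *clec-265* 1.56-fold. The primase subunit gene *pri-2* fell 1.32-fold and the phosphatase gene *lip-1* 1.24-fold (edgeR adjusted p = 0.045 and 0.033).

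In all, 240 of 17627 genes were called in F0, 227 higher and 13 lower in exposed animals. The count rested on single libraries: it was 13, 140 and 112 without exposed replicates 1, 2 and 3, 3 without control replicate 1 and 6 without control replicate 2. A fit of the F0 libraries alone called 10 genes and DESeq2 called 491. DESeq2 did not call *hsp-16.48* and *hsp-16.1*, and the F0 fit called only *acox-1.5*, *linc-142* and *R09E10.2* of the genes named. Without control replicate 1 all named genes but *acox-1.5* and *R09E10.2* lost their calls, as they did without control replicate 2 except that *gst-13* kept its own. Exposed replicate 1 ended the calls of 11 of them, exposed replicate 2 those of *hsp-16.1*, *hrg-4*, *pri-2* and *lip-1*, and exposed replicate 3 those of *hsp-16.48*, *fipr-8*, *hrg-4* and *clec-265*.

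**Figure D1:**
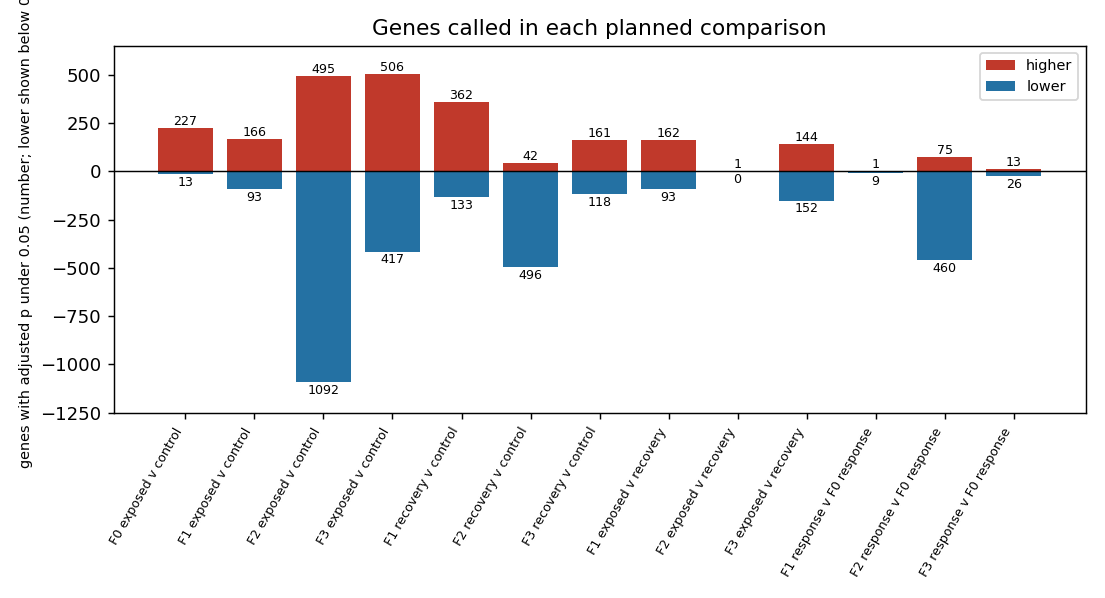
Number of genes called at an adjusted p under 0.05 in each of the 13 planned comparisons, with genes that were higher above 0 and genes that were lower below 0. Exposed against control gave 240, 259, 1587 and 923 calls in F0 to F3, and exposed against recovery gave 1 in F2.

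In F1 the same 2 small heat shock genes were again higher in exposed animals, together with the co-chaperone gene *dnj-13* and the acyl-CoA synthetase genes *acs-1* and *acs-14*. *hsp-16.1* rose 6.19-fold, from 0.729 ± 0.34 to 4.58 ± 0.725 CPM, and *hsp-16.48* 5.67-fold, from 0.704 ± 0.142 to 3.98 ± 0.355 CPM (n = 3; edgeR adjusted p = 0.0045 and 0.0044). *dnj-13* rose 1.35-fold from 342 ± 28.4 to 463 ± 5.36 CPM (log2 fold change 0.43, SE 0.07, edgeR adjusted p = 0.00077). *R09E10.2* rose 4.03-fold to 19.1 ± 1.03 CPM (edgeR adjusted p = 1.4e-07). Of 28 heat shock protein genes 6 were called, all higher (12, again all higher, adjusted over the list alone). This list kept its call with the correlation between genes estimated from the data (camera adjusted p = 2.3e-10, and 0.02 with an estimated correlation).

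Fatty acid genes that rose in F1 included *acs-1*, 1.79-fold from 52 ± 5.58 to 93.1 ± 9.59 CPM, and *acs-14*, 1.51-fold, with *acox-1.5* at 1.53-fold (edgeR adjusted p = 0.00011, 0.0013 and 0.0026). Among 131 cytochrome P450 and UDP-glucuronosyltransferase genes 5 rose and 5 fell (10 and 9 adjusted over the list alone; list adjusted p = 0.95 with an estimated correlation). *cyp-25A2* rose 2.1-fold and *ugt-13* 2.06-fold, while *ugt-48* fell 1.71-fold from 20.6 ± 2.65 to 12 ± 2.27 CPM. The MATH and BTB domain gene *bath-25* rose 6.04-fold, from 1.45 ± 0.579 to 9.03 ± 2.66 CPM. *kreg-1*, *spin-3*, *sdz-24* and *gst-36* rose 2.57-fold, 2.45-fold, 2.35-fold and 1.75-fold. The vitellogenin gene *vit-1* rose 1.4-fold, from 929 ± 57 to 1300 ± 76.4 CPM. Falls included the ferritin gene *ftn-1*, 2.46-fold from 5 ± 0.566 to 2.02 ± 0.197 CPM, the nuclear receptor gene *nhr-206*, 1.92-fold, and *pals-24*, 1.72-fold (edgeR adjusted p = 0.037, 0.0026 and 0.0052).

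The F1 comparison called 259 genes, 166 higher and 93 lower. Leaving out exposed replicate 1 or 2 or control replicate 1 or 2 changed the count, to 93 higher and 26 lower genes in the first case and to 106, 122 and 91 genes in the others, DESeq2 gave 412 and a fit of the F1 libraries alone 705. *ftn-1* lost its call without any 1 of the 6 libraries and with no filter, *pals-24* without exposed replicate 2 and *vit-1* without control replicate 2.

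F2 had the most calls of the 4 generations, 495 higher and 1092 lower, or 1033 and 1013 with DESeq2's size factors as the scaling, and the falls included sperm and cuticle genes. Of 29 major sperm protein genes, which encode the sperm cytoskeleton, 28 were called, all lower (29 adjusted over the list alone; median log2 fold change −0.57). Their sequences are near-identical, so the division of reads among them is uncertain. *msp-76* fell 1.56-fold, from 181 ± 37.4 to 116 ± 4.45 CPM (log2 fold change −0.64, SE 0.12, edgeR adjusted p = 0.0041). Of 64 other sperm genes 31 were called, all lower (48, all lower, adjusted over the list alone; median −0.61), such as *ssp-34* at 1.63-fold, the sperm phosphatase gene *gsp-3* at 1.65-fold and *spe-18* at 2.05-fold. By camera the adjusted p was 5.3e-27 and 3.2e-18 for these 2 lists, and 0.17 and 0.14 as an adjusted p with an estimated correlation.

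Of 154 cuticle collagen genes 47 were called in F2, all lower (87 falls and 2 rises adjusted over the list alone; median log2 fold change −0.74; adjusted p = 8.1e-17, and an adjusted p = 0.36 with an estimated correlation). *col-110* fell 2.09-fold, from 12.9 ± 2.21 to 6.14 ± 1.11 CPM, and *col-46* 3.08-fold (edgeR adjusted p = 0.0053 and 0.0051). The largest fitted fall, 33-fold for *col-2*, rested on control libraries at 0.336, 11.7 and 4.41 CPM against 0.158 ± 0.116 CPM in exposed animals (log2 fold change −5.04, and −3.91 without control replicate 2). The hedgehog-related gene *grl-16* fell 2.29-fold and *abu-11* 2.35-fold. Beside these genes, a cuticle score, the mean log2 CPM of collagen and moulting genes, was 3.18 to 3.82 in the F2 controls and 2.77 to 2.98 in the F2 exposed libraries.

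**Figure D2:**
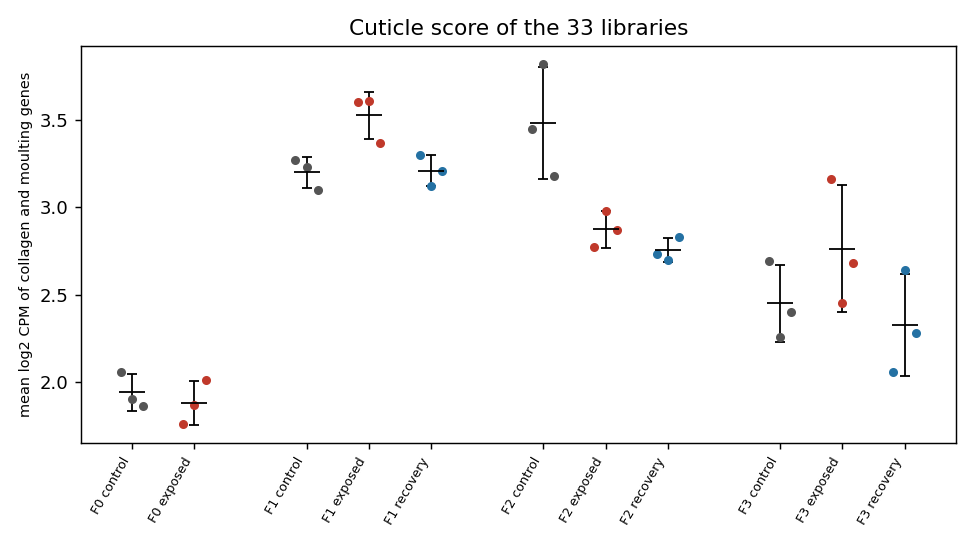
Cuticle score of each of the 33 libraries by group, the mean log2 CPM of cuticle collagen and moulting genes, with points for libraries. Scores lay at 1.76 to 2.06 in F0, 3.1 to 3.61 in F1, 3.18 to 3.82 in the F2 controls, 2.7 to 2.98 in the other F2 libraries and 2.06 to 3.16 in F3.

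Of 57 DNA repair genes 14 were called in F2, all higher (18, all higher, adjusted over the list alone; adjusted p = 3.4e-10, and an adjusted p = 0.36 with an estimated correlation). Their changes were small: *rad-50*, of the MRN complex, rose 1.26-fold from 92.4 ± 6.63 to 116 ± 3.84 CPM, *smc-5* 1.23-fold and *msh-2* 1.22-fold. The replication gene *mcm-5* and the checkpoint kinase gene *atl-1* rose 1.22-fold each, the germ granule helicase gene *glh-1* 1.34-fold and *dcr-1* 1.21-fold. Of 28 heat shock genes 8 rose (8 rises and 1 fall adjusted over the list alone; adjusted p = 0.17 with an estimated correlation). *hsp-70* rose 2.86-fold from 45.3 ± 8.41 to 130 ± 3.4 CPM, *hsp-16.2* 2.78-fold, *hsp-16.41* 2.54-fold, *hsp-90* 1.3-fold and *hsp-16.1* 7.41-fold from 0.13 ± 0.0822 CPM. *R09E10.2* rose 3.05-fold (edgeR adjusted p = 1.3e-05), *hrg-4* 2.39-fold, the P-glycoprotein gene *pgp-1* 2.06-fold and *acox-1.5* 1.62-fold. *ftn-1* fell 3.73-fold, from 4.96 ± 0.751 to 1.33 ± 0.108 CPM, *fbxa-50* 2.81-fold and *ugt-4* 1.89-fold.

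In all, 1587 genes were called in F2. The count was 488, 900 and 849 without exposed replicates 1, 2 and 3, 891 and 109 without control replicates 1 and 2, 2505 with DESeq2, 35 with the cuticle score as a covariate and 974 with the ribosomal RNA share. With the cuticle score as a covariate every gene named for F2 lost its call except *hsp-70*, *hsp-16.2*, *hsp-16.41*, *hsp-90*, *acox-1.5*, *pgp-1* and *R09E10.2*, which kept theirs under each alternative run. Without control replicate 2, *hsp-16.1*, *gsp-3*, *spe-18*, *col-2*, *col-46*, *smc-5*, *msh-2*, *mcm-5*, *atl-1*, *dcr-1*, *grl-16* and *abu-11* lost their calls, and without exposed replicate 1 *hsp-16.1*, *col-2*, *msh-2*, *atl-1* and *abu-11* did, as *col-2* did without exposed replicate 3.

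In F3, the heat shock genes *hsp-16.41* and *hsp-70*, 17 C-type lectin genes and the acyl-CoA oxidase genes *acox-1.5* and *acox-1.1* were higher in exposed animals. Of 28 heat shock genes 5 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.91 with an estimated correlation). *hsp-16.41* rose 3.29-fold, from 83 ± 43 to 273 ± 79.4 CPM, and *hsp-70* 3.11-fold, from 68.9 ± 32 to 215 ± 99.3 CPM (n = 3; edgeR adjusted p = 0.00028 and 0.0012). *acox-1.5* rose 2-fold from 15.3 ± 2.55 to 30.7 ± 1.58 CPM (log2 fold change 1, SE 0.11, edgeR adjusted p = 4.3e-06), with *acs-14* at 1.54-fold and *acox-1.1* at 1.52-fold. Of the 95 lipid metabolism genes 14 rose and 3 fell (21 and 5 adjusted over the list alone; adjusted p = 0.82 with an estimated correlation). *R09E10.2* rose 4.3-fold to 19.8 ± 4.19 CPM (edgeR adjusted p = 6e-08).

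Of 158 C-type lectin genes 17 were called in F3, all higher (24, all higher, adjusted over the list alone; adjusted p = 6.2e-05, and an adjusted p = 0.16 with an estimated correlation). *clec-92* rose 3.75-fold, *clec-180* 3.26-fold, *clec-232* 3.08-fold and *clec-126* 2.07-fold, all from below 2 CPM in controls. Of 17 male marker genes 2 rose (5 adjusted over the list alone; median log2 fold change 0.68; adjusted p = 0.16 with an estimated correlation). These were *mab-3*, from 0.787 ± 0.133 to 1.72 ± 0.393 CPM, and *asic-2*, from 0.296 ± 0.0944 to 1.08 ± 0.62 CPM. In F0 *asic-2* was at 6.69 CPM in exposed and 3.57 CPM in control animals. The peptide transporter gene *pept-1* rose 1.85-fold, *ugt-44* 2.18-fold, the Argonaute gene *csr-1* 1.29-fold, *aat-7* 4.78-fold, *col-41* 6.84-fold, *bath-25* 4.83-fold and *linc-142* 6.96-fold. Falls included *ugt-4*, 3.05-fold from 5.39 ± 0.898 to 1.76 ± 0.2 CPM, *ftn-1* 2.7-fold, *dod-3* 4.09-fold, *fipr-22* 3.29-fold and *nspe-7* 5.11-fold (edgeR adjusted p = 6.9e-05, 0.01, 0.005, 0.0036 and 0.0021). Single libraries moved some of these values, though not past the threshold. Without exposed replicate 1 the log2 fold change of *bath-25* went from 2.27 to 1.27 and that of *clec-180* from 1.71 to 1.13. Without control replicate 2 *clec-92* went from 1.91 to 2.58 and *nspe-7* from −2.35 to −1.68, and without control replicate 3 *linc-142* went from 2.8 to 4.

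The F3 comparison called 923 genes, 506 higher and 417 lower, against 438 without exposed replicate 3. A fit of the F3 libraries alone called 39 genes, and of the genes named it called *acox-1.5*, *acs-14*, *acox-1.1*, *pept-1*, *ugt-4*, *ugt-44*, *col-41*, *aat-7* and *R09E10.2*. Without exposed replicate 3 *ftn-1* and *mab-3* lost their calls, without control replicate 1 *ftn-1* and *asic-2*, and without exposed replicate 1 *asic-2*.

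Averaged over the 4 generations, a contrast chosen after the data were seen, heat shock, glutathione S-transferase and lipid metabolism genes were higher in exposed than in control animals. *R09E10.2*, on chromosome IV at 10317563 to 10318299 on the minus strand (WBcel235), rose 3.94-fold (log2 fold change 1.98, SE 0.09, edgeR adjusted p = 3.1e-15). *acox-1.5*, on chromosome III at 9586618 to 9592192, rose 1.71-fold (log2 fold change 0.78, SE 0.05, edgeR adjusted p = 1.2e-10). *hsp-70* rose 2.43-fold, *hsp-16.41* 2.27-fold and *hsp-16.2* 2.13-fold. Mean levels of *hsp-70* were also higher in unirradiated recovery than in control animals. They were 283 against 183, 88.2 against 45.3 and 151 against 68.9 CPM in F1, F2 and F3. *hsp-16.1* rose 4.44-fold and *hsp-16.48* 3.12-fold on average, although in F3 *hsp-16.48* was at 0.354 ± 0.112 CPM in exposed and 0.532 ± 0.593 CPM in control animals and its second gene at 0.788 ± 0.522 and 0.4 ± 0.378 CPM. Of 28 heat shock genes 10 were called, all higher (14 rises and 2 falls adjusted over the list alone), and of 66 glutathione S-transferase and antioxidant genes 19, all higher (23 rises and 2 falls adjusted over the list alone). Of 95 lipid metabolism genes 26 rose and 3 fell (31 and 11 adjusted over the list alone). These 3 lists had an adjusted p = 0.014, 0.037 and 0.04 with an estimated correlation.

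Also higher in exposed animals over the 4 generations were *elo-2*, a fatty acid elongase gene, 1.64-fold, *ugt-44* 1.62-fold, *cyp-25A2* 1.59-fold, *pept-1* 1.55-fold, *gst-36* 1.5-fold, *acs-14* 1.4-fold and *dnj-13* 1.24-fold. *linc-142* rose 3.34-fold and *bath-25* 3.04-fold. Small average rises were called for *vit-1* at 1.19-fold, *csr-1* at 1.19-fold, *glh-1* at 1.16-fold and *rad-50* at 1.11-fold. *ftn-1* fell 2.64-fold (log2 fold change −1.4, SE 0.17, edgeR adjusted p = 2.5e-06), *ugt-4* 1.89-fold and *dod-3* 2.16-fold. This contrast called 1462 genes, 974 higher and 488 lower, and stayed between 1169 and 1892 under every alternative run. In the separate generations 12 genes were higher in all 4 and 1 was lower in all 4. Of the 12, *hrg-4* rose 2.33-fold on average, the AN1 zinc finger gene *aip-1* 1.78-fold, the peroxisomal transporter gene *pmp-1* 1.61-fold and the peroxisomal enzyme gene *dhs-28* 1.24-fold, genes that were chosen after their values were seen.

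**Figure D3:**
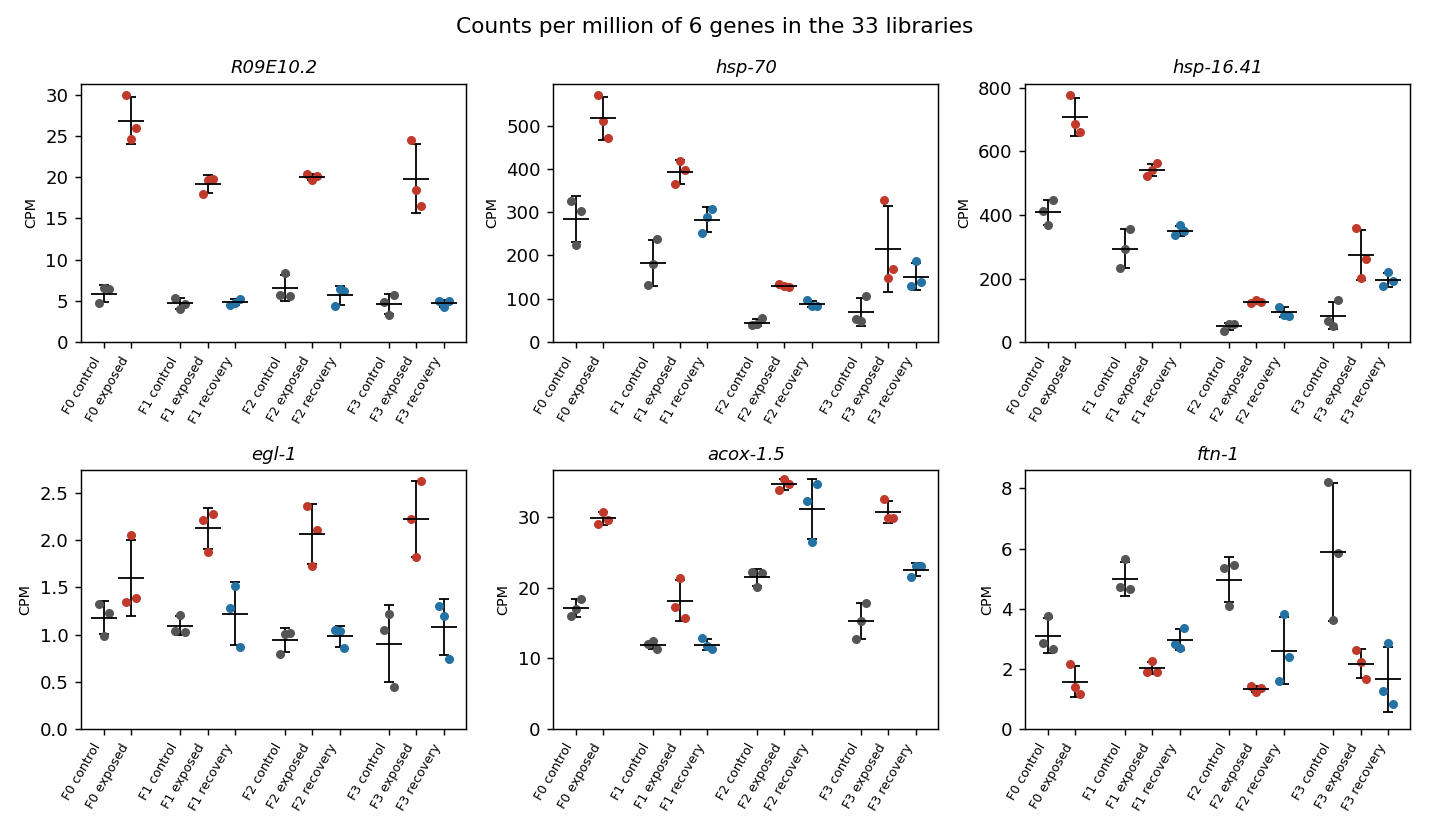
Levels in CPM of 6 genes in each of the 33 libraries, with points for libraries, a dash for the group mean and bars for the SD (n = 3). *R09E10.2* averaged 19.1 to 26.9 CPM in the 4 exposed groups and 4.62 to 6.55 CPM in the control and recovery groups.

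The p53 homologue gene *cep-1* and its known apoptotic targets *egl-1* and *ced-13* were examined in each generation. *egl-1*, on chromosome V at 14431308 to 14432359, was at 1.6 ± 0.4 CPM in exposed and 1.18 ± 0.176 CPM in control animals in F0 (log2 fold change 0.43, SE 0.26, edgeR adjusted p = 0.42). In F1 the values were 2.13 ± 0.216 and 1.09 ± 0.0964 CPM (0.96, SE 0.26, edgeR adjusted p = 0.057). *egl-1* rose 2.15-fold in F2 (1.11, SE 0.27, edgeR adjusted p = 0.01) and 2.48-fold in F3 (1.31, SE 0.27, edgeR adjusted p = 0.0045). The average over the 4 generations was a 1.94-fold rise (0.95, SE 0.13, edgeR adjusted p = 1.5e-05). Recovery animals gave *egl-1* log2 fold changes against control of 0.17, 0.04 and 0.28 in F1, F2 and F3 (edgeR adjusted p = 0.85, 0.96 and 0.65). Against recovery, *egl-1* in exposed animals differed by 0.79, 1.07 and 1.03 on the log2 scale, past the threshold in F3 (edgeR adjusted p = 0.11, 0.42 and 0.042). *cep-1* passed the threshold in no exposed against control comparison, with log2 fold changes of 0.01, 0.01, 0.19 and −0.09 (edgeR adjusted p = 0.97, 0.98, 0.19 and 0.64). *ced-13* had at most 4 counts in any library and was not tested. The F2 call of *egl-1* ended without exposed replicate 1 or control replicate 2 (log2 fold change 1 and 1.15, edgeR adjusted p = 0.061 each) and with the cuticle score as a covariate (1.06, edgeR adjusted p = 0.16), and the F3 call ended in a fit of the F3 libraries alone (1.31, edgeR adjusted p = 0.21). Against recovery in F3 it ended without exposed replicate 1 or 3 or recovery replicate 1 or 3 (log2 fold change 1.04, 0.9, 1.21 and 0.83, edgeR adjusted p = 0.13, 0.15, 0.053 and 0.19), in the F3 fit, with either covariate and without the 2 libraries with few genes detected.

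The second question was whether descendants of animals irradiated in F0 alone differed from controls. In F1 recovery animals, the developmental timing gene *lin-42* rose 2.1-fold, from 9.89 ± 0.847 to 20.8 ± 0.641 CPM (log2 fold change 1.07, SE 0.15, edgeR adjusted p = 0.00011). The SMAD gene *daf-8* rose 2.09-fold, *linc-81* 2.35-fold, the nucleotide excision repair helicase gene *xpd-1* 1.79-fold, *cdk-2* 1.64-fold and the poly(A) polymerase gene *gld-4* 1.47-fold. *apc-17* fell 2.9-fold, from 4.69 ± 0.439 to 1.61 ± 0.0923 CPM (log2 fold change −1.54, SE 0.23, edgeR adjusted p = 0.00018). Of 350 F-box, MATH and Skp1-related genes 17 were called, all higher (35 higher and 2 lower adjusted over the list alone; adjusted p = 0.22 with an estimated correlation), such as *fbxb-98* at 2.57-fold and *fbxb-93* at 2-fold. The aspartyl protease gene *asp-6* fell 1.57-fold, from 2000 ± 164 to 1270 ± 123 CPM. The C-type lectin genes *clec-47* and *clec-48* fell 1.67-fold and 1.56-fold. The thaumatin gene *thn-1* fell 2.27-fold. Of 80 neuropeptide genes 6 were called, all lower (17, all lower, adjusted over the list alone; adjusted p = 0.22 with an estimated correlation), among them *nlp-13* at 1.43-fold and *flp-22* at 1.41-fold.

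*R09E10.2* was at 4.85 ± 0.355 CPM in F1 recovery and 4.71 ± 0.668 CPM in F1 control animals (edgeR adjusted p = 0.98). F1 recovery against control called 495 genes, 362 higher and 133 lower. Without recovery replicates 1 and 2 the count was 254 and 187, without control replicates 1 and 2 it was 222 and 204, and F1 libraries alone gave 1024. *flp-22*, *thn-1*, *fbxb-98*, *nlp-13* and *clec-47* lost their calls without 1 or more of these libraries, and *flp-22* also without recovery replicate 3 or control replicate 3.

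The F2 recovery animals had falls among cuticle and moulting genes. Of 154 cuticle collagen genes 50 were called, all lower (91 falls and 2 rises adjusted over the list alone; median log2 fold change −0.89), and of 90 moulting and hedgehog-related genes 16 were called, all lower (38, all lower, adjusted over the list alone; median −0.55). These lists had an adjusted p = 0.39 and 0.32 with an estimated correlation. *col-110* fell 2.49-fold from 12.9 ± 2.21 to 5.16 ± 1.16 CPM, *col-10* 2.06-fold, *col-46* 3.57-fold and *dpy-8* 4.62-fold (edgeR adjusted p = 0.0048, 0.0043, 0.0065 and 0.023). The moulting gene *mlt-10* fell 2.19-fold from 22.1 ± 5.24 to 10 ± 1 CPM, *mlt-9* 2.47-fold, *grd-1* 1.91-fold and the metalloprotease gene *zmp-2* 3.09-fold. The cuticle score was 2.7 to 2.83 in F2 recovery against 3.18 to 3.82 in F2 control libraries. *clec-230* fell 3.46-fold and *phat-2* 2.31-fold, whereas *hpo-15* rose 1.64-fold, *pmp-1* 1.51-fold, *acox-1.5* 1.45-fold and *hrg-4* 1.99-fold. *R09E10.2* was at 5.69 ± 1.17 CPM against 6.55 ± 1.55 CPM in controls (edgeR adjusted p = 0.55).

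F2 recovery against control called 538 genes, 42 higher and 496 lower, or 115 and 369 with DESeq2's size factors. Counts were 26, 49 and 164 without recovery replicates 1, 2 and 3, 131, 14 and 1174 without control replicates 1, 2 and 3, 1107 with DESeq2, 1012 from F2 libraries alone, 297 with no filter, 354 with a stricter filter, 97 with the ribosomal RNA share and 1 with the cuticle score as a covariate, which ended the call of every gene named. Without control replicate 2 every named gene but *col-110*, *mlt-10*, *clec-230* and *hpo-15* lost its call, and without recovery replicate 1 *col-46*, *mlt-9*, *clec-230*, *pmp-1*, *acox-1.5*, *hrg-4*, *phat-2*, *zmp-2* and *dpy-8* did. Recovery replicate 2 ended the calls of *mlt-9*, *grd-1* and *dpy-8*, and recovery replicate 3 those of *acox-1.5*, *hrg-4* and *dpy-8*.

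In F3 recovery animals, *ugt-4* fell 3.41-fold, from 5.39 ± 0.898 to 1.56 ± 0.266 CPM (log2 fold change −1.77, SE 0.21, edgeR adjusted p = 3.7e-05). *ftn-1* fell 3.62-fold (log2 fold change −1.86, and −2.47 without recovery replicate 2) and *dod-3* 4.15-fold. *hrg-4* rose 2.59-fold from 2.41 ± 0.512 to 6.23 ± 1.11 CPM, *hsp-16.41* 2.36-fold, *ugt-44* 1.79-fold, *pept-1* 1.71-fold, *acs-14* 1.47-fold and *acox-1.5* 1.47-fold. *cutl-18* rose 3.03-fold, *gtr-1* 2.71-fold and *math-20* 1.54-fold. Of 28 heat shock genes 3 rose (5 rises and 1 fall adjusted over the list alone; adjusted p = 0.88 with an estimated correlation). *R09E10.2* was at 4.72 ± 0.412 CPM in recovery and 4.62 ± 1.25 CPM in control animals (edgeR adjusted p = 0.94).

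F3 recovery against control called 279 genes, 161 higher and 118 lower. Each library moved this count, to 109, 882 and 26 without recovery replicates 1, 2 and 3 and 68, 918 and 122 without control replicates 1, 2 and 3, and it was 31 without the 2 libraries with few genes detected, 528 with DESeq2, 72 with the ribosomal RNA share and 1 from F3 libraries alone, when *ugt-4* alone of the genes named kept its call. Without the 2 libraries *ftn-1*, *dod-3*, *acs-14*, *cutl-18*, *gtr-1*, *math-20* and *pept-1* lost their calls. Recovery replicate 3 decided the calls of *ftn-1*, *dod-3*, *hsp-16.41*, *acox-1.5*, *ugt-44*, *gtr-1*, *math-20* and *pept-1*, control replicate 1 those of *dod-3*, *hsp-16.41*, *acox-1.5* and *pept-1*, and recovery replicate 1 those of *dod-3* and *pept-1*.

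The mean of the 3 recovery against control differences, also chosen after the data were seen, gave a 1.9-fold rise of *hrg-4* (log2 fold change 0.93, SE 0.13, edgeR adjusted p = 0.00048). *hsp-70* rose 1.87-fold, *hsp-16.41* 1.74-fold, *ugt-44* 1.43-fold, *acox-1.5* 1.29-fold and *dnj-13* 1.21-fold. *ftn-1* fell 2.27-fold and *ugt-4* 1.73-fold (edgeR adjusted p = 0.0013 and 0.00037). The contrast called 510 genes, 234 higher and 276 lower, or 332 and 246 with DESeq2's size factors. The count was 175, 245 and 293 without F1 recovery replicates 1, 2 and 3, 252 and 186 without F1 control replicates 1 and 2, and 154 and 259 without F2 recovery replicates 1 and 3. It was 254, 190 and 1201 without F2 control replicates 1, 2 and 3, 243, 1094 and 214 without F3 recovery replicates 1, 2 and 3, and 173 and 1867 without F3 control replicates 1 and 2. DESeq2 gave 1144, no filter 336, the cuticle score 37, the ribosomal RNA share 52 and the libraries without the 2 with few genes detected 234, and the 8 genes named here kept their calls in all of these.

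The third question was how continued irradiation differed from recovery in the same generation. In F1, *hsp-16.48* was 5.13-fold higher in exposed than in recovery animals, 3.98 ± 0.355 against 0.78 ± 0.0951 CPM, and *hsp-16.1* 4.49-fold higher (edgeR adjusted p = 0.0081 and 0.016). *apc-17* was 2.76-fold higher, *gst-26* 1.69-fold, the collagen gene *col-178* 1.66-fold, *acox-1.5* 1.52-fold, *acs-14* 1.46-fold, *asp-6* 1.4-fold, *clec-149* 1.4-fold and *vit-4* 1.39-fold. Lower in exposed animals were *fbxb-57*, 2.04-fold, *cng-1*, 1.8-fold, and *fbxa-182*, 1.64-fold. Of 350 F-box, MATH and Skp1-related genes 9 were called, all lower (32 lower and 3 higher adjusted over the list alone), and of 66 glutathione S-transferase and antioxidant genes 3, all higher (8, all higher, adjusted over the list alone). Both lists had an adjusted p = 0.048 with an estimated correlation. The F1 count was 255, 162 higher and 93 lower, and fell to 27 without exposed replicate 2, when *gst-26*, *acox-1.5*, *acs-14*, *asp-6*, *cng-1*, *fbxa-182*, *fbxb-57* and *hsp-16.1* lost their calls. It was 117, 51 and 73 without recovery replicates 1, 2 and 3, 495 with DESeq2 and 704 from F1 libraries alone. Without recovery replicate 3 *hsp-16.1*, *fbxa-182* and *clec-149* lost their calls, without recovery replicate 2 *hsp-16.1* and *fbxb-57*, without recovery replicate 1 *hsp-16.1*, and without exposed replicate 3 *fbxb-57*.

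In F2, *R09E10.2* was the only gene called between exposed and recovery animals by edgeR, at 20 ± 0.366 against 5.69 ± 1.17 CPM (log2 fold change 1.82, SE 0.18, edgeR adjusted p = 8.5e-07). DESeq2 also called 1 gene, and 1150 genes had an unadjusted p under 0.05 in edgeR. Without exposed replicate 3 or recovery replicate 1 the count was 2 and 3, and it was 2 from F2 libraries alone. The same gene was 3.96-fold higher in exposed than in recovery animals in F1 and 4.19-fold higher in F3 (edgeR adjusted p = 1.4e-07 and 5.9e-08).

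In F3, the metallothionein gene *mtl-2* was 2.71-fold higher in exposed than in recovery animals, 14.1 ± 1.96 against 5.18 ± 1.55 CPM (edgeR adjusted p = 0.012). *vmo-1* was 3.58-fold higher, *clec-95* 3.42-fold, *clec-126* 1.79-fold and *acox-1.5* 1.37-fold, and *nspe-7* was 4.86-fold lower. Of 158 C-type lectin genes 8 were higher and 1 lower (19 and 1 adjusted over the list alone; adjusted p = 0.45 with an estimated correlation). The count was 296, 144 higher and 152 lower. It was 18, 986 and 8 without exposed replicates 1, 2 and 3, 75 higher and 29 lower without recovery replicate 1, 898 and 3 without recovery replicates 2 and 3, 809 with DESeq2, 128 with no filter, 46 with the ribosomal RNA share, 7 without the 2 libraries with few genes detected, and 1 both from F3 libraries alone and with the cuticle score, when *R09E10.2* alone of the genes named kept its call. Without recovery replicate 3 every named gene but *vmo-1* and *R09E10.2* lost its call. The same happened to *clec-95*, *clec-126*, *nspe-7* and *acox-1.5* without exposed replicate 1, to *mtl-2*, *clec-95*, *clec-126*, *nspe-7* and *acox-1.5* without exposed replicate 3, and to *clec-126* and *acox-1.5* without recovery replicate 1.

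**Figure D4:**
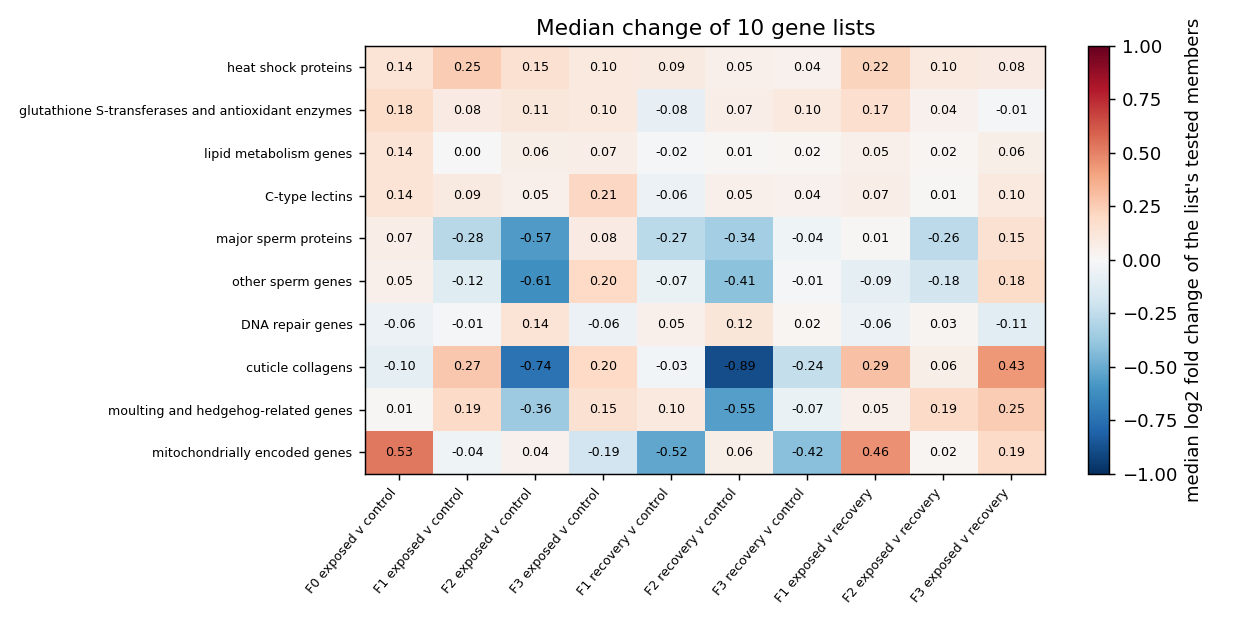
Median log2 fold change of the tested members of 10 gene lists in the 10 comparisons within a generation, where red is higher and blue lower in the group named first. The cuticle collagens had medians of −0.74 and −0.89 in F2 exposed and F2 recovery animals against F2 controls, and the major sperm proteins −0.57 in F2 exposed animals.

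Finally, the question was whether the response to irradiation in later generations differed from that in F0, tested as a difference of differences. Cuticle scores also differed between generations, at 1.76 to 2.06 in F0 and 3.1 to 3.61 in F1. A changed response may therefore follow the stage at sampling as well as the generation, and the design cannot tell these apart. Against F0, 10 genes differed in F1, 1 with a higher and 9 with a lower response. *srh-237* had a response 1.84-fold lower (log2 difference −0.88, SE 0.14, edgeR adjusted p = 0.0055), from 13.2 ± 0.815 to 15.7 ± 1.29 CPM in F0 and from 20.2 ± 0.674 to 13 ± 0.447 CPM in F1. *ugt-48* and *clec-4* had responses 2.08-fold and 2.39-fold lower, and the nuclear receptor gene *nhr-6* 2.78-fold higher. The count was 2 without F0 exposed replicate 1 and without F0 control replicate 1 or 2, 4 and 3 without F1 exposed replicates 1 and 3, and 3, 4 and 16 without F1 control replicates 1, 2 and 3. It was 50 with DESeq2, 81 from F0 and F1 libraries alone and 2 with the ribosomal RNA share. Only *srh-237* of the 4 genes kept its call without each of these libraries.

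In F2, 535 genes differed, 75 with a higher and 460 with a lower response, or 171 and 373 with DESeq2's size factors. Of 29 major sperm protein genes 14 had a lower response in F2 (29 adjusted over the list alone; adjusted p = 0.26 with an estimated correlation), and *msp-76* was 1.64-fold lower (log2 difference −0.71, SE 0.16, edgeR adjusted p = 0.022). Responses were lower for *dpy-20*, 3.99-fold, *fipr-10*, 2.21-fold, *nspd-10*, 1.87-fold, and *tni-1*, 1.63-fold. They were higher for *fbxa-182*, 1.83-fold, and the RNA editing gene *adr-1*, 1.43-fold. The count was 105, 180 and 304 without F2 exposed replicates 1, 2 and 3, 1 and 271 without F0 control replicates 1 and 2, 2 without F2 control replicate 2, and 0 without F0 exposed replicate 1. DESeq2 called 1149 genes, a fit of the F0 and F2 libraries 1233, the ribosomal RNA share left 50 and the cuticle score 1. All 7 genes lost their calls without F0 exposed replicate 1, F0 control replicate 1 or F2 control replicate 2 and with the cuticle score, as did *msp-76* and *fbxa-182* without F2 exposed replicate 2.

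In F3, 39 genes differed, 13 with a higher and 26 with a lower response. The polyamine synthesis gene *odc-1* was 1.84-fold and *vglu-3* 2.56-fold higher, and *fipr-8* was 3.06-fold and *spp-22* 1.84-fold lower (edgeR adjusted p = 0.016, 0.035, 0.043 and 0.033). The count was 0 without F0 exposed replicate 1 or F0 control replicate 1, 17 and 14 without F0 exposed replicates 2 and 3, and 9 and 15 without F0 control replicates 2 and 3. It was 347, 2 and 7 without F3 exposed replicates 1, 2 and 3, and 14, 365 and 7 without F3 control replicates 1, 2 and 3. DESeq2 called 176 genes, the stricter filter left 12, the cuticle score gave 197, the fit without the 2 libraries with few genes detected 12 and F0 and F3 libraries alone 0. All 4 genes lost their calls without F0 exposed replicate 1, F0 control replicate 1 or F3 exposed replicate 2.

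Genes called in exposed animals were shared between generations, whose controls were separate libraries. Of those higher, 47 were common to F0 and F1 and 61 to F1 and F3, where independent lists of these sizes would share 2.1 and 4.8. F2 and F3 shared 52 higher genes (14 for independent lists) and 23 lower ones (26 for independent lists), and 31 genes were called in opposite directions. Over all tested genes, fold changes of exposed generations correlated at 0.07 to 0.28, and at −0.04 for F2 with F3. Of the genes called in F2, 33.8% had the same sign in F3. For the other pairs of exposed generations this share of the earlier generation's calls was 74.1% to 83.3%. Recovery animals of F1 and F2 shared 0 higher genes and 1 lower gene (0.86 and 3.7 for independent lists), those of F1 and F3 shared 3 and 2 (3.3 and 0.89), and those of F2 and F3 shared 7 and 7 (0.38 and 3.3). The numbers called in opposite directions were 8, 1 and 3. F0 exposed animals and recovery animals of F1, F2 and F3, again with separate controls, shared 1, 11 and 23 higher genes. Independent lists would share 4.7, 0.54 and 2.1. Lower genes shared were 1, 0 and 0, and 6, 2 and 1 genes were called in opposite directions. Within a generation, exposed and recovery animals had 41 calls in common in F1, 342 in F2 and 184 in F3, each in the same direction in both, and independent lists in F2 would share 1.2 higher and 31 lower genes against the 32 and 310 observed.

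Those comparisons used the same controls, so the fold changes were also set beside 20 simulations of unchanged groups against the same number of shared controls. Across genes, which are not independent replicates, the correlation of exposed and recovery fold changes was 0.52, 0.78 and 0.54 in F1, F2 and F3, and 0.52, 0.52 and 0.51 on average in simulation. The covariance exceeded the simulated one by 0.016, 0.096 and 0.058. The share of genes with the same sign in both was 67.2%, 79.4% and 61.7%, against 67%, 67.1% and 66.9% in simulation, so that in F3 it lay below the value for unchanged groups. The 3 control libraries of a generation were too few for parts of at least 2 libraries each and were not split, so part of the excess overlap and covariance may come from them. The simulated genes were drawn independently, so shifts that many genes share within a control library were absent from the simulations. Every group was also simulated with the same dispersion per gene. Between real control replicates the chi-square per degree of freedom was 15.6 to 68.8 in F1, 83.9 to 145.3 in F2 and 38.6 to 125.4 in F3. The simulations therefore cannot tell the larger excess in F2 and F3 from a larger spread of those controls.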

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

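The differences between generations were planned, whereas the other splits of the libraries, the tests of explanations, the 2 covariates and the averages over generations were chosen after results had been seen. The response to irradiation differed from that in F0 for 10 genes in F1, 535 in F2 and 39 in F3, each by a test of the difference itself. Of 60 splits of the libraries drawn within generations, the real one included, 6 gave as many genes as the 10 in F1, with up to 144 in the others, and 13 gave as many as the 39 in F3, with up to 1210. Chance was therefore not excluded for F1 and F3. For F2 only the real split, 1 of 60, reached 535 genes, with 501 as the highest of the others. These splits mix exposed and control libraries in both generations, so they stand for no response in either. They cannot exclude chance for a difference between responses that are both present. The average over the 4 exposed generations, 1462 genes, was reached by 1 of 60 splits, the real one, with 450 as the highest other. That share is under 0.05 where no generation responds. The contrast was chosen after the data were seen, so chance was not taken as excluded here either. The average over the 3 recovery generations, 510 genes, was reached by 2 of 60, a share under 0.05. The other of these 2 splits called 3145 genes, several times the real number. A split apart from the treatment can thus call more genes, so chance was not taken as excluded.

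For comparisons of 3 libraries with 3, the 10 possible splits are too few for a share under 0.05. Exposed against control gave 240, 259 and 1587 genes in F0, F1 and F2, where 1 split of 10 reached the real number and the highest other gave 0. In F3 it gave 923, 2 splits reached that number and the highest other gave 2715. Recovery against control gave 495 and 538 genes in F1 and F2 (1 split each, highest other 0) and 279 in F3 (2 splits, highest other 1836). Exposed against recovery gave 255 in F1 (1 split, highest other 0), 1 in F2 (2 splits, highest other 2) and 296 in F3 (1 split, highest other 269). The split with 2715 genes set F3 exposed replicate 1 and control replicates 1 and 3 against the rest, and the one with 1836 set F3 recovery replicates 1 and 3 and control replicate 2 against the rest. Both follow the share of ribosomal RNA counts, which was 20.8% in F3 exposed replicate 1, 15.7% and 14% in control replicates 1 and 3 and 10.2% in recovery replicate 2, against 4.09% to 6.8% in the other 5 F3 libraries. The F3 libraries therefore hold a structure that is not the treatment, and with the ribosomal RNA share as a covariate the F3 counts were 1248 for exposed and 72 for recovery against control.

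F2 exposed and F2 recovery animals both differed from the F2 controls, and 342 genes were called in both. As the cause of this F2 pattern as a set, an effect of the F0 exposure that the recovery line carried through F1 to F3 is argued against, though not for single genes such as *hrg-4*, *hsp-70*, *ftn-1* and *ugt-4*, which were called in the recovery average: the 538 genes called in F2 recovery moved by −7.75% of their F2 size in F1 (quartiles −21.2% and 8%) and by 4.01% in F3 (quartiles −17.2% and 27.2%). A difference in developmental stage between the F2 controls and the other F2 libraries is a candidate explanation: with the cuticle score as a covariate, the median size over 472 genes outside the collagen and moulting lists went from 0.83 to 0.41 (SE 0.21 and 0.26), 49.3% of its value, just under the bound of 50% that was set, with quartiles of 34% and 71.9%, and none of the 472 was still called, because the change shrank and its error grew. Ribosomal RNA content stays open, as its covariate left 84.6% of the size (0.9 to 0.77; quartiles 78.3% and 91.4%) and 90 of 538 calls, above the bound of 80% but not beyond the spread. A stage difference that irradiation or its inheritance produced in F2 alone was not tested and cannot be told apart from one that arose in the 3 control cultures.

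F3 recovery replicate 3 and F3 control replicate 3 had the fewest genes detected, 18240 and 19610. Their depth argues against low sequencing, with 42.8 and 38.9 M counts against a median of 31.4 M in the other F3 libraries. In recovery replicate 3 the zeros matched an effective number of reads of 14.4% of the total, against 57.6% to 88.1% in the other F3 libraries, while genes at 0.1 to 0.5 CPM summed to 111% of their level elsewhere, so few distinct molecules copied many times may explain it. For control replicate 3 the values were 33.4% and 105%, the first above the bound of 25% set for the test, and the same explanation stays open. No biological explanation was tested, as the design sets neither library apart.

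In F3, 17 C-type lectin genes and 2 male markers were called higher in exposed than in control animals. A shift in cuticle stage is argued against: with the cuticle covariate the median change of the 19 called genes went from 1.3 to 1.12 (SE 0.31 and 0.3), 85.8% of its size, with quartiles per gene of 91.9% and 103%, and 14 of 19 were still called. A few males among the exposed animals might raise both groups, since the male markers had a median log2 fold change of 0.68 and lay above all 3 controls in 3 of 3 libraries. Their adjusted p = 0.16 with an estimated correlation leaves this open, and *asic-2* of that list was higher in both F0 groups than in F3. Against F3 recovery the male markers had a median of 0.61, with 15 higher and 2 lower (camera adjusted p = 0.093 with an estimated correlation). Of 29 major sperm protein genes 26 were higher in F3 exposed than in control animals, with a median of 0.08 and 0 called. An effect of 4 generations of exposure is also open, since no test separated it from the presence of males.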

How the results depend on the processing

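The cuticle and ribosomal RNA covariates, the fit without F3 recovery replicate 3 and F3 control replicate 3, and the averages over generations were chosen after the data were seen, and the other alternatives before. Counts of called genes moved far more than the single strong genes chosen for the text, and the cause was not tested. A smaller number of libraries did not act in 1 direction. Fits of the libraries of 1 generation gave more calls in the F1 comparisons and fewer in those of F0 and F3. Of 204 called results for genes in the text, DESeq2 lost 2 and no filter 3, the stricter filter lost 1 of the 159 it tested, and the size factors of DESeq2 lost 0. Fits of the generations compared kept 115 of 168, the cuticle covariate 150, the ribosomal RNA covariate 192 and the fit without the 2 F3 libraries 70 of 85. With the fits without 1 library counted too, 100 of the 204 results were kept in every planned setting. None of the 204 changed sign in any of these settings. The text preferred genes whose calls held in other settings, so these shares do not describe all named genes. For exposed against control, the fixed rule named 36, 45, 106 and 69 called genes in F0, F1, F2 and F3. Of these, 1, 17, 6 and 8 kept their calls in every setting. Elsewhere the share ran from 0 of 50 in F2 recovery against control to 69 of 99 for the average over exposed generations.

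Without 1 library at a time, exposed against control called 3 to 350 genes in F0, 91 to 204 in F1, 109 to 2313 in F2 and 438 to 1223 in F3. Recovery against control called 187 to 477, 14 to 1174 and 26 to 918 in F1, F2 and F3, and exposed against recovery 27 to 214, 1 to 3 and 3 to 986. The response differed from F0 for 2 to 16, 0 to 751 and 0 to 365 genes in F1, F2 and F3. The averages called 1216 to 1892 genes over 4 exposed generations and 154 to 1867 over 3 recovery generations. For *egl-1* these fits gave log2 fold changes against control of 0.22 to 0.54, 0.91 to 1.05, 1 to 1.22 and 0.96 to 1.64 in exposed animals of F0 to F3. In recovery animals of F1 to F3 they gave 0 to 0.35, −0.04 to 0.13 and −0.07 to 0.6, and between exposed and recovery animals 0.61 to 0.96, 0.96 to 1.18 and 0.83 to 1.21.

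DESeq2 called 491, 412 and 2505 genes for exposed against control in F0, F1 and F2, 1107 and 528 for recovery against control in F2 and F3, and 495 and 809 for exposed against recovery in F1 and F3. For the differences between generations it called 50, 1149 and 176, and for the recovery average 1144. *egl-1* in F1 exposed against control passed the threshold (0.97, DESeq2 adjusted p = 0.023). Overlaps of DESeq2 calls between exposed generations were 85 for F0 and F1, 125 for F0 and F2, 90 for F0 and F3, 110 for F1 and F2, 127 for F1 and F3 and 133 for F2 and F3. Between recovery generations they were 4, 13 and 50 for F1 and F2, F1 and F3, and F2 and F3, and between exposed and recovery animals 87, 720 and 291 in F1, F2 and F3.

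With the libraries of the compared generations alone, exposed against control gave 10, 705 and 39 genes in F0, F1 and F3, recovery against control 1024, 1012 and 1 in F1 to F3, and exposed against recovery 704, 2 and 1. The differences between generations gave 81, 1233 and 0. *egl-1* passed the threshold in F1 against control (0.97, edgeR adjusted p = 0.019) and against recovery (0.79, edgeR adjusted p = 0.037), and missed it in F3 against control (1.31, edgeR adjusted p = 0.21) and against recovery (1.05, edgeR adjusted p = 0.35). With no filter, recovery against control in F2 gave 297 genes, exposed against recovery in F3 128 and the recovery average 336. The stricter filter gave 354 genes for recovery against control in F2 and 12 for the F3 difference from F0.

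The replicate number as a block gave 86 genes in F0 exposed against control, 304 and 127 in F2 and F3 recovery against control, 45 in F3 exposed against recovery, 0, 285 and 10 for the differences between generations and 210 for the recovery average. With the block *egl-1* in F3 exposed against recovery was at 1.08 (edgeR adjusted p = 0.077). Libraries with the same number in different groups did not deviate together: in 0 of 10 pairs of groups were all correlations of their deviations over 0.1, with a range of −0.22 to 0.33, so the numbers were not treated as pairs. Of the 204 gene results 188 kept their calls with the block, and list calls numbered 203.

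With the cuticle covariate, exposed against control in F2 gave 35 genes, recovery against control in F2 1, exposed against recovery in F3 1, the differences from F0 1 in F2 and 197 in F3, and the recovery average 37. *egl-1* was at 1.06 in F2 against control (edgeR adjusted p = 0.16), 1.06 in F3 against recovery (edgeR adjusted p = 0.27) and −0.01 in F2 recovery against control. The ribosomal RNA covariate gave 974 genes in F2 exposed against control, 97 and 72 in F2 and F3 recovery against control, 46 in F3 exposed against recovery, 2 and 50 for the F1 and F2 differences from F0 and 52 for the recovery average. With it *egl-1* was at 1.1 in F3 against recovery (edgeR adjusted p = 0.06) and −0.04 in F2 recovery against control. Without the 2 F3 libraries, recovery against control in F3 gave 31 genes, exposed against recovery 7, the F3 difference from F0 12 and the recovery average 234, and *egl-1* in F3 against recovery was at 0.82 (edgeR adjusted p = 0.11).

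Signs changed only in results that had not been called. *cep-1* against control was at −0.01, −0.04 and 0.03 in F0, F2 and F3 with the cuticle covariate, and at −0.15 in F1 with the ribosomal RNA covariate. It was at −0.04 and −0.02 in F0 without exposed replicate 1 and control replicate 2, at 0, −0.07 and 0 in F1 without exposed replicate 1, control replicate 2 and control replicate 3, and at 0.03 and 0.04 in F3 without exposed replicate 1 and control replicate 2, with highest and lowest values of 0.09 in F1 and −0.16 in F3 without 1 library. *R09E10.2* in recovery against control was at −0.03 and −0.06 in F1 without recovery replicate 3 and control replicate 2, at 0.06 in F2 with the cuticle covariate and 0 without control replicate 2, and at −0.01 and −0.18 in F3 without recovery replicate 3 and control replicate 2. The other ends of its ranges without 1 library were 0.14, −0.32 and 0.23 in F1, F2 and F3. *egl-1* in recovery against control was at 0 in F1 without recovery replicate 2, at 0 in F2 without recovery replicate 1 or 2, at −0.04 in F2 without control replicate 1 and at −0.07 in F3 without control replicate 3.

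The list tests gave 204 calls over 13 comparisons with the preset correlation, 3 with an estimated one and 58 with fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes. Depth limited *ced-13*, with 0 to 4 counts per library, and genes of few counts such as *hsp-16.1* and *egl-1*, with group means of 0.13 to 4.58 CPM and 0.903 to 2.23 CPM.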

Other observations

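The list results here come from planned tests, except that the average over recovery generations was chosen, and the list of mitochondrially encoded genes rebuilt, after the data were seen. In the F2 exposed animals, further lists beside the sperm, collagen and repair genes had called members, though none of these lists was called with an estimated correlation. Of 33 proteasome subunit genes 6 were called, all higher (14, all higher, adjusted over the list alone; median log2 fold change 0.14; adjusted p = 0.37 with an estimated correlation). Of 44 small RNA pathway genes 8 rose and 2 fell (11 and 2 adjusted over the list alone; adjusted p = 0.36 with an estimated correlation), and of 44 DNA replication and cell cycle genes 7 were called, all higher (10 adjusted over the list alone; adjusted p = 0.36 with an estimated correlation). Of 19 pharynx markers 5 were called, all lower (8 lower and 1 higher adjusted over the list alone; median −0.41; adjusted p = 0.37 with an estimated correlation), and in F2 recovery animals 7 were, all lower (7 adjusted over the list alone; median −0.4; adjusted p = 0.39 with an estimated correlation). The cuticle score differed between the same groups of libraries.

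In F1, the 6 vitellogenin genes, which encode yolk proteins, had a median log2 fold change of 0.37 in exposed against recovery animals, with 2 called higher (6 adjusted over the list alone; adjusted p = 0.067 with an estimated correlation). The F3 exposed animals had 4 rises and 10 falls among 131 cytochrome P450 and UDP-glucuronosyltransferase genes (4 and 20 adjusted over the list alone; adjusted p = 0.91 with an estimated correlation), and the F3 recovery animals 2 and 7 (5 and 12 adjusted over the list alone; adjusted p = 0.88 with an estimated correlation). Averaged over the 3 recovery generations, 4 of 12 mitochondrially encoded genes were called, all lower than in controls (8, all lower, adjusted over the list alone; median −0.27; adjusted p = 0.26 with an estimated correlation).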
